A study of Homo sapiens with 2 samples.

How the data were processed

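Gene expression was measured in MCF-7 cells, an established estrogen receptor-positive human breast cancer line, on the Affymetrix Human Genome U133 Plus 2.0 array. The shSMYD3 culture carried a lentiviral short hairpin RNA against SMYD3, which encodes a SET and MYND domain lysine methyltransferase. The control culture carried a hairpin against luciferase, a gene that human cells lack. Per the labels' protocols, both were grown in medium with 10% fetal bovine serum and selected with 1 microgram per ml puromycin for 3 days, and total RNA was extracted with Trizol and labelled by the standard Affymetrix procedure. Each group has 1 array.

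The values are those of the deposited value table, a linear signal intensity for each of 54675 probe sets on each array, as deposited by the authors. The software that made them is not given in the sources used here. The mean after trimming 2% of the values at each end was 500.1 on both arrays, which is how a global scaling to a common target leaves a table. The median signal was 97.5 on the shLuc array and 100.0 on the shSMYD3 array, a difference of 0.04 on the log2 scale. As this was under the limit of 0.1 that had been set, the deposited scaling was kept. The table carries no detection calls and no separate background values.

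Signals were converted to log2 after values below 1 had been set to 1, which affected 45 probe sets on the shLuc array and 79 on the shSMYD3 array. The 62 Affymetrix control probe sets were left out of all gene results. Probe sets were named through the platform annotation paired with the table. Of the others, 41091 had 1 gene symbol, 1801 had several and 11721 had none, and only those with 1 symbol were named. Among all probe sets with 1 symbol, 41043 had an Entrez identifier in the RefSeq table of assembly GRCh38.p14, 54 did not, and none of the symbols differed between both sources. A gene was represented by its probe set with the highest mean log2 signal. It was kept if this mean reached 6.57, the median over all non-control probe sets, which corresponds to a linear signal of 95.2. This left 11830 of 19775 genes, of which 5966 had at least 2 probe sets above the limit. All log2 ratios are shSMYD3 over shLuc. Positions in the genome are not given, because the array table names no genome build.

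With 1 array per group there is no replicate error and no p-value. Genes were counted by size, at 2-fold or more in either direction. For each gene list, the median log2 ratio of its members above the level limit was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins, and under the alternatives among 2000. A list was said to stand apart below the 2.5th or above the 97.5th percentile, and needed at least 5 members. These percentiles describe these 2 arrays and do not test the condition. The number of arrays limits the precision throughout. The only error within the data is the disagreement between different probe sets of a gene on the same arrays. From the difference between the 2 brightest probe sets of 5966 genes, 1 probe set's log2 ratio had an SD of 0.31. This spread can also hold differences between transcripts, leaves out errors that both probe sets share, and does not measure variation between cultures. Intervals of list medians are 95% bootstrap intervals over member genes from 2000 draws.

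The 40 lists, the rules and the alternatives were fixed before the data were examined. The genes named are SMYD3, the 15 highest and the 15 lowest genes whose probe sets above the limit all had the same sign, and up to 2 members at each end of every list. Genes named outside this rule were chosen after their values were seen and are marked as such. The alternatives were quantile normalization, a loess of log2 ratio on level with a span of 0.3, an offset of 32 added to the signal, no level limit, a limit at the 75th percentile, the median over a gene's probe sets, probe sets with _s_at or _x_at endings left out, and a 1.5-fold threshold. Such endings mark probe sets that can detect several transcripts or related genes.

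The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The procedure was tested on simulated data, with 200 of 11830 genes changed on a pair of arrays built from the real levels and the probe set SD. For the shSMYD3 against shLuc comparison, the 2-fold rule counted 96% of genes changed by 1.5 on the log2 scale, 100% of those changed by 2.5 and 0.043% of unchanged genes. Of 100 lists of 25 unchanged genes, 3% fell outside the percentile range. The simulated noise had the same SD at every level, was independent between genes and held no variation between cultures. The real spread was wider among dim genes, so these shares are not error rates of the real arrays. They also tell nothing about lists whose genes vary together.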

Results

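The series compared MCF-7 breast cancer cells with a hairpin against SMYD3 to cells with a luciferase hairpin, to profile expression after knockdown of this histone methyltransferase. The data are 2 arrays, 1 shLuc and 1 shSMYD3, so there is no replicate error and no p-value. The signals ranged from 0.2 to 44204.5 on the shLuc array and from 0.3 to 47361.8 on the shSMYD3 array. Over the 11830 genes above the level limit, the log2 signals of both arrays correlated with a Pearson r of 0.96 across genes, which are not independent replicates. The median log2 ratio was 0.02 and the SD was 0.51, against the probe set SD of 0.31 from 5966 of these genes.

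SMYD3 itself was lower on the array labelled shSMYD3. Its single probe set, which has an _s_at ending, read 1082 on the shLuc array and 371.0 on the shSMYD3 array. This is 34.3% of the control signal and a log2 ratio of -1.54, against a probe set SD of 0.31. Among the 1000 genes nearest to it in level, 5 had a log2 ratio as low or lower, SMYD3 included. Among other SMYD family members and lysine methyltransferases, 29 genes were above the level limit, 15 higher and 14 lower. The histone H3 lysine 9 methyltransferase SUV39H1 had a log2 ratio of -0.91 and NSD2 of -0.81, while KMT5C stood at 1.14 and KMT2C at 0.50. The list median of 0.12 lay at the 85.3rd percentile of random lists. The probe sets of NSD2 did not all have the same sign. Those ending in _s_at were all lower, from -0.18 to -1.01. The only other probe set, at 344.1 on the shLuc array against 1665.7 for the brightest, had a log2 ratio of 0.07. KMT5C read only 79.0 on the shLuc array, below the level limit.

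By size, 339 genes were at least 2-fold higher on the shSMYD3 array and 331 were at least 2-fold lower, together 5.66% of the genes above the limit. At 4-fold, the numbers were 20 and 9. The spread was wider among dim genes. Over the 2958 dimmest genes above the limit the SD of the log2 ratio was 0.61 and 282 genes passed 2-fold, while over the 2958 brightest the SD was 0.40 and 74 genes passed. Of 271 genes past 2-fold that had a second probe set above the limit, 252 had the same sign in that probe set. In 183 it passed 1.5-fold the same way and in 99 it passed 2-fold. Across the 5966 genes with 2 such probe sets, 71.1% had the same sign in both. The log2 ratios of both probe sets correlated with a Pearson r of 0.60 and a Spearman rho of 0.57.

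**Figure D1:**
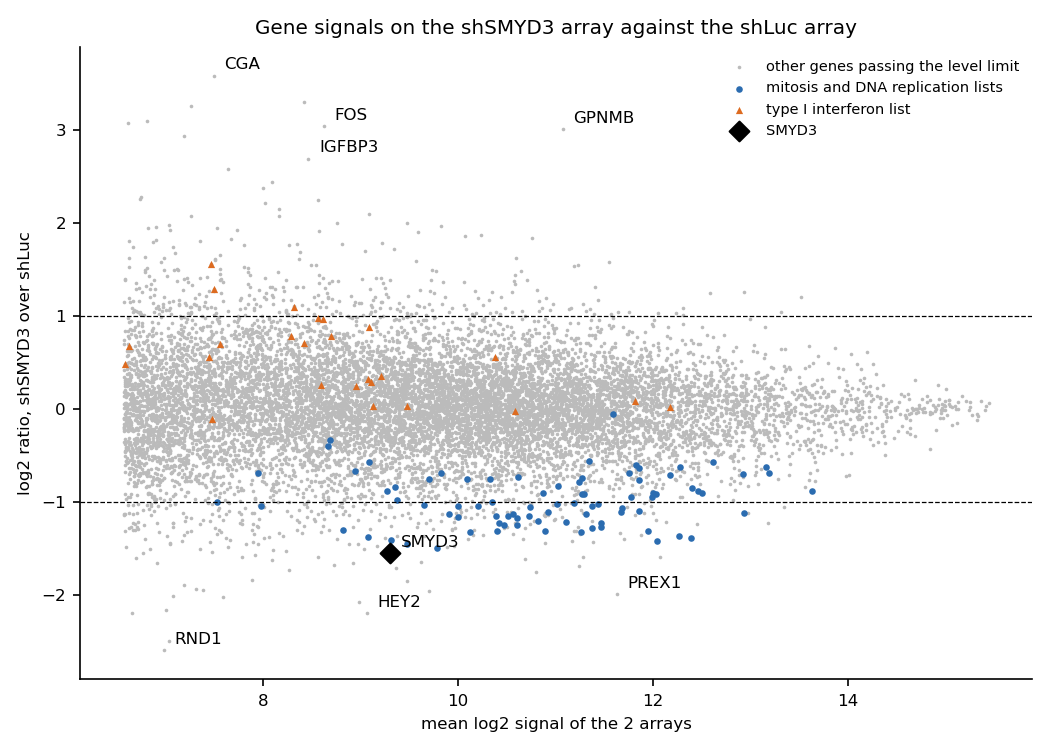
Log2 ratio of the shSMYD3 over the shLuc array (vertical axis) against the mean log2 signal of both arrays (horizontal axis) for the 11830 genes above the level limit, 1 point per gene, with dashed lines at 2-fold. The 84 genes of the mitosis and DNA replication lists all lie below 0, and SMYD3 lies at -1.54.

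Genes of cell division were lower on the shSMYD3 array. All 45 genes of the mitosis list lay below 0, 29 of them by at least 2-fold and 44 by at least 1.5-fold, with a median log2 ratio of -1.09 (95% bootstrap interval -1.15 to -1.01 over genes). The kinetochore motor CENPE read 1482 on the shLuc array and 526.2 on the shSMYD3 array, a log2 ratio of -1.49. The spindle midzone protein PRC1 stood at -1.41. At the other end, CKS2, a subunit of cyclin-dependent kinases, stood at -0.63 and the phosphatase CDC25B at -0.05. The proliferation marker MKI67, chosen after its value was seen, had a log2 ratio of -1.02 with 4 probe sets of the same sign. All 39 measured genes of the DNA replication list were lower as well, 14 of them by at least 2-fold, with a median of -0.84 (interval -1.01 to -0.71). CDC6, which loads the replicative helicase, stood at -1.45 and the helicase cofactor CDC45 at -1.41, while GINS3 stood at -0.33 and CHAF1B at -0.39. None of 10000 random lists had a median as low as either list. In the list of cyclins and cell cycle inhibitors, the members lay on both sides of 0. Cyclin D1 (CCND1) stood at -1.13 and cyclin E1 (CCNE1) at -0.84, while CCNG2 and the pocket protein RBL2 both stood at 0.96. The dimmest CCNG2 probe set had the opposite sign, at -0.75, and the others stood at 0.87 to 1.24. That list's median was 0.07, at the 67.2nd percentile.

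Estrogen-responsive genes were mostly lower. Of 38 measured members, 32 lay below 0 and 10 were at least 2-fold lower, with a median of -0.54 (interval -0.76 to -0.20), lower than all 10000 random lists. The members shared no gene with the mitosis and replication lists, but this does not show that the differences arose separately. RAPGEFL1 had the lowest log2 ratio, at -1.65, followed by MYBL1, a MYB family transcription factor, at -1.39. Of the 6 members above 0, FOS, an immediate early transcription factor, stood at 3.04, and the growth factor receptor IGF1R was next at 0.43. Well-known targets chosen after their values were seen differed from each other. The progesterone receptor gene PGR stood at -1.03, while TFF1 stood at -0.10 and GREB1 at 0.25 with probe sets of opposite sign. The luminal identity list, which holds the estrogen receptor gene ESR1, had a median of 0.02 at the 57.9th percentile. In it SPDEF stood at -0.93 and PRLR at -0.92, while the epithelial transcription factor ELF3 stood at 1.22 and the mucin MUC1 at 0.77. The bright SPDEF probe sets stood at -0.79 to -0.93, and dim ones near the level limit had the opposite sign, at 0.07 and 0.24. ESR1, also chosen after its value was seen, had a log2 ratio of -0.44, and its 7 probe sets above the limit differed in sign.

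**Figure D2:**
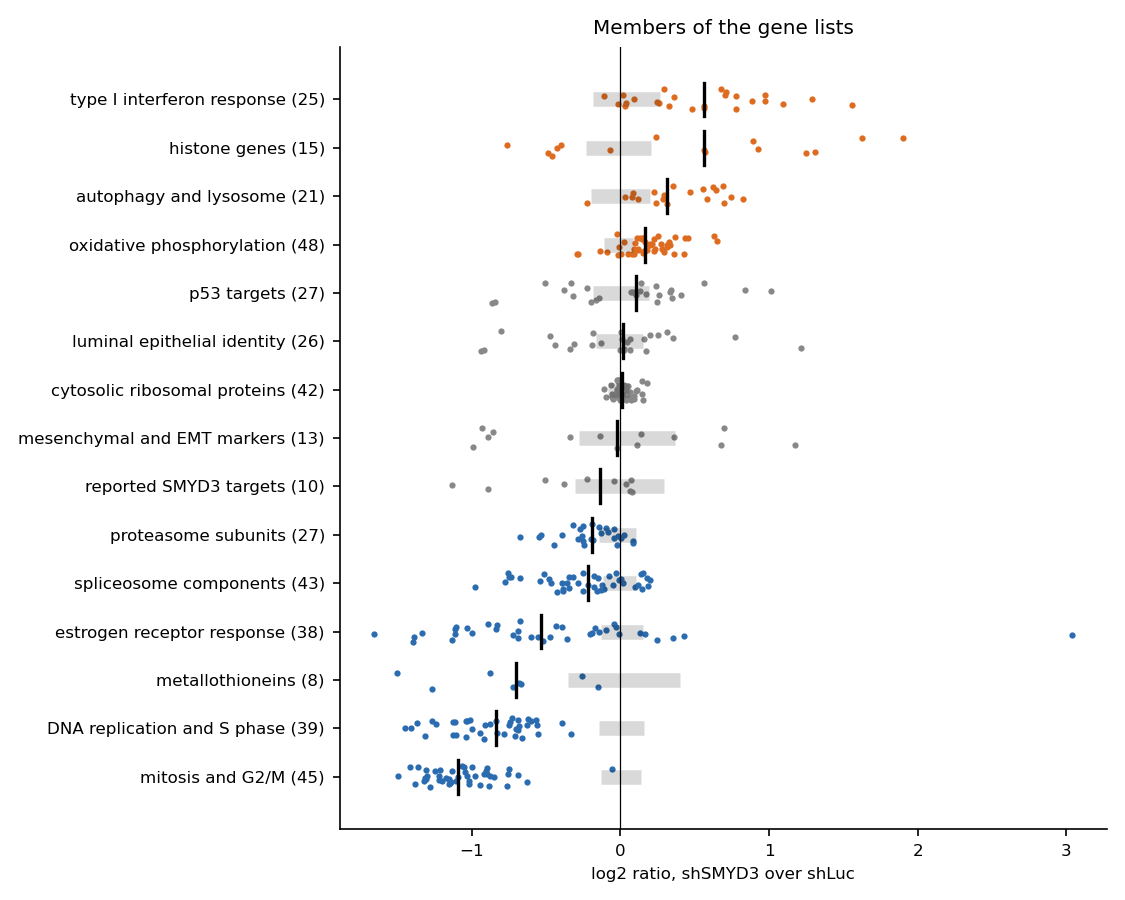
Log2 ratio of the shSMYD3 over the shLuc array (horizontal axis) for the members of the 10 lists that stood apart, blue where lower and orange where higher, and of 5 lists that did not, in grey, with the number of measured members in brackets. Each point is a gene, black bars are list medians and pale bars span the middle 95% of medians of level-matched random lists, so that the mitosis median of -1.09 and the interferon median of 0.56 lie outside them.

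Type I interferon response genes were higher on the shSMYD3 array. Of 25 measured members 23 lay above 0 and 3 reached 2-fold, with a median of 0.56 (interval 0.26 to 0.78), and none of the 10000 random lists reached this. IFIT1, an interferon-induced RNA-binding protein, read 103.1 on the shLuc array and 303.9 on the shSMYD3 array, a log2 ratio of 1.56. OAS1, which senses double-stranded RNA, stood at 1.29, while IFIT3 stood at -0.11, with probe sets of opposite sign, and IFITM1 at -0.02. With the level limit at the 75th percentile the median was 0.25 and lay at the 92.7th percentile, so the list no longer stood apart. Genes of antigen presentation had a median of 0.23 at the 93.1st percentile. Among them PSMB9 stood at 0.94, HLA-DMA at 0.79, HLA-F at -0.12 and TAP2 at -0.03, the last pair with probe sets of opposite sign. HLA-DMA read 89.3 on the shLuc array, below the level limit.

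Autophagy and lysosome genes were modestly higher, 20 of 21 above 0 with none past 2-fold and a median of 0.31 (interval 0.24 to 0.59) at the 99.9th percentile. The lysosomal protease CTSB stood at 0.82 and the lysosomal calcium channel MCOLN1 at 0.75, while ATG5, with probe sets of opposite sign, stood at -0.22 and LAMP2 at 0.03. Without the probe sets that can detect several transcripts, this median was 0.13 at the 77.2nd percentile. Oxidative phosphorylation genes lay slightly higher, 41 of 48 above 0 with a median of 0.17 (interval 0.13 to 0.22), above all random lists. SDHC stood at 0.65, NDUFB5 at 0.63, NDUFB10 at -0.29 and NDUFB6 at -0.29, the last with probe sets of opposite sign.

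Of the 15 measured histone genes, 9 lay above 0, 4 of them by at least 2-fold, and 6 below. The clustered H2A gene H2AC8 read 397.2 on the shLuc array and 1488 on the shSMYD3 array, a log2 ratio of 1.91, and the linker histone gene H1-2 stood at 1.62. The variant histone genes H2AX and H2AZ1 stood at -0.76 and -0.49, and the probe sets of H2AX differed in sign. The list's median of 0.56 lay above all random lists, but its bootstrap interval of -0.40 to 0.94 spans 0. Clustered histone genes are close copies of each other, so a probe set can detect several of them.

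Genes of the metallothionein list were lower in all 8 members measured, with a median of -0.70 (interval -1.27 to -0.26) at the 0.06th percentile. MT1H read 885.9 on the shLuc array and 312.5 on the shSMYD3 array. MT1X stood at -1.27, MT3 at -0.15 and MT1F at -0.26. A dimmer MT1F probe set, also above the limit, stood at -1.37. Metallothioneins bind zinc and copper and are close paralogs, so their probe sets can share signal. The list also holds the zinc transporter gene SLC30A1, chosen after its value was seen, which is not a metallothionein and stood at -0.72 with probe sets of opposite sign. Spliceosome components had a median of -0.22 at the 0.04th percentile, 33 of 43 lower, with SF3B3 at -0.98 and SNRPA1 at -0.78 against SF3B4 at 0.20 and SRSF11 at 0.19. Proteasome subunits had a median of -0.19 at the 0.63rd percentile, 23 of 27 lower, with PSMD1 at -0.67 and PSMD3 at -0.55 against PSMD6 and PSMB4, both at 0.08. The probe sets of SNRPA1 and of PSMB4 differed in sign. For SNRPA1, those with _s_at or _x_at endings stood at -0.78 to -1.21, and the only other one, the dimmest, stood at 0.24. Neither of the last 2 lists had a gene past 2-fold, and both no longer stood apart without _s_at and _x_at probe sets, at the 3.85th and the 6.1st percentile.

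Genes that have been reported as SMYD3 targets in other systems did not stand apart as a list. Of the 16 genes listed, 15 were on the array and 10 were above the level limit, so this holds for these 10 only. Among these 10 members, 6 lay below 0 and 4 above, with a median of -0.14 at the 17.2nd percentile. Reported targets that were below the limit or absent from the array did not enter this median, and it tells nothing about them. CCND1 stood at -1.13 and the matrix metalloproteinase MMP9 at -0.89, while CTNNB1 stood at 0.08 and MET, with probe sets of opposite sign, at 0.07. The 9 measured genes of metalloproteinases and their inhibitors had a median of 0.06, with TIMP3 at -1.16 and MMP14 at 0.79. Mesenchymal and EMT markers, of which 13 were above the level limit, had a median of -0.02. In this list CCN1 stood at -0.99, TGFBI at -0.93, COL6A2 at 1.17 and FBN1 at 0.70, the last pair below 95.2 on the shLuc array. The second probe sets above the limit stood at 0.05 for COL6A2 and at -0.13 for CCN1. Basal epithelial markers had a median of 0.02, but ANXA1 stood at 2.37 and the caveolin gene CAV1 at 1.84, and CD44 stood at -0.79.

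Targets of p53, which is wild type in this line, had a median of 0.10 at the 83.5th percentile, with TP53INP1 at 1.02, TP53I3 at 0.84, AEN at -0.86 and GDF15 at -0.84. The Notch pathway list had a median of -0.19 at the 5.93rd percentile. Its members HEY2 and NRARP stood at -2.19 and -1.16, and HES1 at 1.03. The remaining lists lay within the range of random lists, between the 2.85th percentile for NRF2 targets and the 91.6th for apoptosis regulators. Their medians were -0.01 for ATF4 and amino acid response genes, 0.01 for NF-kB and inflammatory genes, -0.04 for immediate early genes, -0.05 for RAS-MAPK feedback genes, -0.07 for WNT targets and 0.06 for TGF-beta targets. They were -0.20 for cholesterol biosynthesis, -0.26 for fatty acid synthesis, -0.12 for the unfolded protein response, -0.06 for hypoxia and glycolysis and -0.20 for NRF2 targets. They were -0.16 for heat shock proteins, 0.16 for apoptosis regulators, 0.01 for cytosolic ribosomal proteins, -0.06 for the RNA interference machinery and -0.15 for stem and progenitor markers. Some of their members were past 2-fold. The aldo-keto reductase gene AKR1C3, an NRF2 target, stood at 2.10, the glycolytic gene ALDOC at 1.48 and the WNT target RNF43 at 1.36, while the amino acid transporter genes SLC3A2 and SLC7A5 stood at -1.20 and -1.11 and the lipid transfer gene STARD4 at -1.14. In all, 6 of the 36 lists with enough members stood apart below and 4 above. If the lists held unrelated genes, 1.8 would be expected outside the range. Genes of a list can vary together between any 2 cultures, so 1.8 is not a chance level for these lists.

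Of the 15 highest and the 15 lowest genes, HEY2, FOS and ANXA1 belonged to the lists above. The lowest log2 ratios were those of the Rho family GTPase RND1, at -2.59, the peroxisomal oxidase ACOX2, at -2.49, the hydroxycarboxylic acid receptor HCAR3, at -2.40, and the glutamate receptor subunit GRIK5, at -2.19. All 4 read between 47.1 and 65.3 on the shSMYD3 array, below the level limit of 95.2, and their order rested on these dim signals. With an offset of 32 on the signal HEY2 had the lowest log2 ratio, at -2.05, and RND1 stood at -2.04, ACOX2 at -1.98, PREX1 at -1.96, HCAR3 at -1.96, ARSJ at -1.94 and GRIK5 at -1.64. Brighter on both arrays were PREX1, an activator of Rac GTPases, which read 6312 on the shLuc array and 1594 on the shSMYD3 array and had a log2 ratio of -1.99 in both of its probe sets, and the Notch effector HEY2, which read 1148 and 252.0. ARSJ stood at -2.07, the metallothionein gene MT1HL1 at -1.95 and DDIAS at -1.85, each from over 1000 on the shLuc array. For MT1HL1 and GRIK5, the only probe set above the limit had an _x_at ending, so it can detect related genes. The remaining members of the lowest 15 were MYRIP at -2.16, the neuropeptide gene NMU at -2.02, the myosin light chain kinase gene MYLK at -1.94, the iron reductase gene CYBRD1 at -1.93, GNB1L at -1.89, and SMTNL2, which read 270.6 on the shLuc array and 67.5 on the shSMYD3 array. Of these, all but NMU read below 95.2 on the shSMYD3 array. For MYRIP, MYLK and GNB1L, at least 1 dimmer probe set under the level limit had the opposite sign.

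The highest log2 ratio without an offset was that of CGA, the shared alpha subunit of the glycoprotein hormones, which read 52.3 on the shLuc array and 625.8 on the shSMYD3 array, a log2 ratio of 3.58. GPNMB, a transmembrane glycoprotein of endosomes and lysosomes, was the brightest of the highest 15, with 760.0 on the shLuc array and 6125 on the shSMYD3 array, 8.06-fold higher, and its second probe set had a log2 ratio of 2.02. FOS read 137.4 on the shLuc array and 1130 on the shSMYD3 array in its single probe set, a log2 ratio of 3.04. The insulin-like growth factor binding protein gene IGFBP3 stood at 2.69, the transcription factor MAF at 2.44, ANXA1 at 2.37 and the protease inhibitor gene CSTA at 2.25. The noncoding RNA LINC02806 stood at 3.30, and its second probe set above the limit at 2.42. The others were SPAM1 at 3.26, GTF2IP20 at 3.10, HMGCLL1 at 3.07, DPY19L2 at 2.93, FSIP2 at 2.58, ZDHHC11 at 2.28 and CYP4V2 at 2.26, all of which read below 95.2 on the shLuc array. GTF2IP20 and ZDHHC11 rested on a single probe set with an _x_at ending, which can detect related genes. For ANXA1 and CYP4V2, at least 1 dimmer probe set under the level limit had the opposite sign. With an offset of 32 on the signal, LINC02806 had the highest log2 ratio, at 2.97, CGA and GPNMB both stood at 2.96, SPAM1 at 2.64, GTF2IP20 at 2.36 and HMGCLL1 at 2.26.

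**Figure D3:**
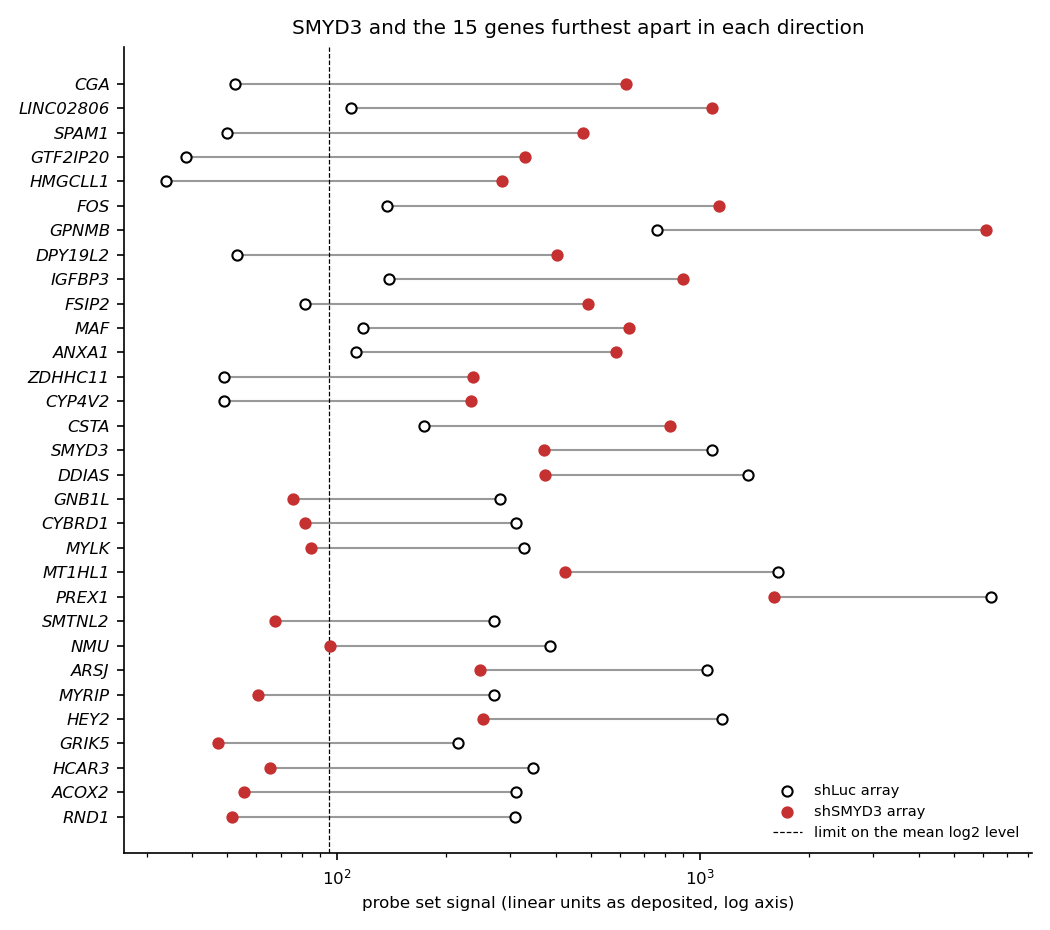
Probe set signal on the shLuc array (open points) and the shSMYD3 array (red points) for SMYD3 and the 15 genes furthest apart in each direction, on a log axis, with the level limit of 95.2 as a dashed line. GPNMB and PREX1 lie well above the limit on both arrays, while CGA, at 52.3 on the shLuc array, and RND1, at 51.5 on the shSMYD3 array, cross it.

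The control probe sets and markers of other cells gave the background to these differences. The 3' over 5' signal ratio, which rises when RNA is degraded, was 1.05 on the shLuc array and 1.08 on the shSMYD3 array for GAPDH, and 1.40 and 1.47 for ACTB. The 18 probe sets of the hybridization spikes had a median log2 ratio of 0.10, with values from -0.53 to 0.29, and the 24 of the poly-A spikes also 0.10, with values from -0.29 to 0.28. Too few markers of other cells were above the level limit to place their lists. These were 4 of 13 fibroblast, 2 of 14 leukocyte, 3 of 11 endothelial and 2 of 8 HEK293 markers on the array, none of them past 2-fold. The brightest, MGP and COL1A1, were chosen after their values were seen. They read 513.9 and 483.4 on the shLuc array and 485.6 and 772.8 on the shSMYD3 array, and the probe sets of COL1A1 differed in sign.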

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

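The test of the scaling was set before its value was seen, and the test of RNA quality only after. For culture differences, the prediction written beforehand needed a second shLuc culture, which the series lacks, so it was not tested. Among 4850 probe sets above the level limit that have no single gene symbol and entered no comparison, 183 were at least 2-fold higher on the shSMYD3 array and 89 were at least 2-fold lower. They drew attention because they hold signal outside the named genes, and no biological explanation was tested for them.

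The genes of the mitosis and replication lists, 84 together, all lay below 0, with a median log2 ratio of -1.01. A trend of the ratio with signal level is argued against as the whole cause, since the median after a loess on level was -1.02. RNA degradation on the shSMYD3 array is argued against too, since the 3' over 5' ratios of GAPDH and ACTB differed by at most 0.077 on the log2 scale. What stays open is whether the knockdown of SMYD3 or another difference between the cultures, such as density, hairpin off-target effects, the response to selection or the time of harvest, lowered these genes. With 1 shLuc array the median of -1.01 cannot be told apart from the variation between control cultures.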

How the results depend on the processing

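No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out. The SMYD3 log2 ratio stayed between -1.59 and -1.47 under every alternative run on it. As SMYD3 has a single probe set, the median over probe sets could only return the main value. The alternative without _s_at and _x_at probe sets was not run on it, because its probe set has an _s_at ending. The count of genes past 2-fold depended on the level limit. Without it 1557 genes were higher and 1737 lower, and with the limit at the 75th percentile 119 were higher and 176 lower. At 1.5-fold, 1265 genes were higher and 1247 lower. Among genes with at least 2 probe sets above the limit, an alternative chosen after seeing the data, 33 had all of them at least 2-fold higher and 36 all at least 2-fold lower, where fewer genes could qualify. The other scalings, offset, probe set choices and a limit on both arrays, the last also chosen after seeing the data, gave 248 to 304 higher and 249 to 372 lower genes. Of the 331 lower genes, 328 remained under quantile normalization and 247 with the offset. Of 248 list medians under alternatives, 5 left the bootstrap interval of the main value and none of a list that stood apart changed sign. The 5 were the interferon list with the limit at the 75th percentile, at 0.25; without _s_at and _x_at probe sets, antigen presentation at 0.49, autophagy and lysosome at 0.13 and ribosomal proteins at -0.0185; and ribosomal proteins after loess, at 0.055. Under alternatives 13 medians of 7 lists within the random range changed sign. Over all settings these medians spanned -0.15 to 0.18 for basal markers, -0.16 to 0.10 for cyclins and inhibitors, -0.28 to 0.26 for RAS-MAPK feedback genes, -0.08 to 0.12 for SMYD family members and methyltransferases, -0.06 to 0.25 for metalloproteinases, -0.0055 to 0.07 for TGF-beta targets and -0.0185 to 0.055 for ribosomal proteins. In 7 cases a list crossed the percentile range. Beyond those in the report these were proteasome subunits with the median over probe sets, at the 4.5th percentile, fatty acid synthesis without a limit, at the 0.55th, and heat shock proteins with the median over probe sets, at the 1.25th. The causes were not tested. The mitosis, replication, estrogen, histone and oxidative phosphorylation lists stood apart under every alternative, and the metallothionein list under every one that gave a value. Under 5 members, and so no median, were left for metallothioneins and reported SMYD3 targets without _s_at and _x_at probe sets, and for metalloproteinases and NF-kB genes at the 75th percentile limit. Of 752 values of named genes under alternatives, 51 moved by more than the probe set SD, and none of those past 2-fold changed sign. Of those under 2-fold, 8 changed sign. With the median over probe sets IFIT3 was at 0.51, MET at -0.29, ERN1 at -0.11, HLA-F at 0.06 and NDUFB6 at 0.05. Without _s_at and _x_at probe sets, chosen for single genes after seeing the data, NDUFB6 was at 0.40, NSD2 at 0.07, SNRPA1 at 0.24 and NFKB2 at -0.06. Dim genes limit what can be read from these arrays, as the table has no detection calls.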

Other observations

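The gene lists described here were written after the highest genes of the comparison had been seen but before the lists' own values were, and members held in the 40 lists or named in the report were left out. The neighbour test without histone genes, the comparison of the share of bright cilium genes with random lists, and the alternatives run on these lists were chosen only after results were seen, and the genes named here were chosen after their values were seen.

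Genes of the cilium were higher on the shSMYD3 array. Among 58 measured genes of intraflagellar transport and the primary cilium, 44 lay above 0 and 8 were at least 2-fold higher with none 2-fold lower, and the median log2 ratio was 0.47 (95% bootstrap interval 0.22 to 0.57). The intraflagellar transport gene IFT172 stood at 1.44, CLUAP1 at 1.36, the kinesin-associated gene KIFAP3 at 1.35 and the Bardet-Biedl syndrome gene BBS12 at 1.37, while DYNC2I2 stood at -0.55. Among 34 genes of the axoneme and motile cilium, 22 lay above 0 and 4 were at least 2-fold higher, with a median of 0.34, and an interval of -0.0042 to 0.76 that reaches below 0. DNAI4 stood at 1.53, CFAP44 at 1.37 and DNAAF5 at -0.91. Lysosomal genes that TFEB and MITF are known to control also lay higher, 24 of 32 above 0 with a median of 0.26, among them the chloride transporter CLCN7 at 1.12 and the sialidase NEU1 at 1.05. Of 16 FOXO target genes 14 lay above 0, with a median of 0.37, TNFSF10 at 1.46 and KLHL24 at 1.00.

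The ciliary genes that drew attention were DNAAF4, SPEF2, CFAP69, WDR19, DYNC2LI1 and NME5, with log2 ratios from 1.78 to 2.21, and none of them is in either list. A candidate reading is that ciliary genes are higher as a class, and the lower of both lists' percentiles among level-matched random lists was 99.97. With the level limit at the 75th percentile, the axoneme list lay at the 96.05th percentile and no longer stood apart, while the intraflagellar transport list stood apart under all 7 alternatives. Weak probe sets that vary more stay open for both lists together. The 33 intraflagellar transport genes above the 75th percentile of level had a median of 0.46, at the 100th percentile of random lists. This argues against weak probe sets as the whole cause for these 33 genes. The 48 cilium genes above the 75th percentile of level had a median log2 ratio of 0.38, which none of 10000 level-matched random lists reached, but 64.6% of them were above 0, short of the 75% set beforehand, and 601 of the 10000 random lists had as high a share.

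The TFEB and MITF list lay at the 99.76th percentile and the FOXO list at the 99.28th, without the genes that had drawn attention to them, GPNMB (3.01) and RRAGD (1.97) for the first and CREBRF (2.00), CCNG2 (0.96) and RBL2 (0.96) for the second, and both stood apart under all 7 alternatives. The autophagy and lysosome list of the report did not, at the 77.2nd percentile without _s_at and _x_at probe sets. Protein levels or localization of these factors were not measured.

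Neighbouring genes on a chromosome had slightly similar log2 ratios. Across 11809 genes in the order of the GRCh38.p14 RefSeq table the correlation between neighbours was 0.05, and none of 1000 shuffled gene orders reached it. The highest running median of 25 neighbours, 0.68, began at TRIM38 and was reached by none of the 1000 shuffles, as a first version of this test had asked for a difference in copy number. This window held 17 histone genes, whose own median was 0.82, and the test was then repeated without histone genes. The highest window ran from CARF to IKZF2, with a median of 0.53 that 13 of 1000 shuffles reached, and the lowest ran from PRR12 to KLK1, with a median of -0.43 that 142 reached. Chromosome segments that differ in copy number between the 2 cell populations could give such a window, but 6 of its 25 genes lay below 0 and no DNA was measured, so the value of 0.53 leaves this open.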
